A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

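RNA was measured in 4 libraries of Escherichia coli K-12 MG1655, the reference laboratory strain, in 2 groups of 2. The group N_plus grew in 50 mL shaken cultures (220 rpm, 37 °C) of M9 minimal medium, a defined salt medium, with 9.35 mM NH4Cl as the nitrogen source, to an optical density of 0.2. The group N_minus_5h was taken after such cells had been spun down, washed, moved to the same medium with 0.935 mM NH4Cl and incubated for 5 h. The labels' protocol calls the starting culture mid-exponential and the design text calls it early exponential. Per the labels' protocols, the RNA was treated with DNase and made into strand-specific total RNA libraries after removal of ribosomal RNA. The replicate numbers in the labels do not say whether 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

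The values used here are those of the authors' own comparison of both groups, a table with 1 log fold change, 1 p-value and 1 Benjamini-Hochberg adjusted p-value per gene, per the file headers. HISAT2, Subread, featureCounts and edgeR are named in the submitters' processing notes, with no versions, roles or order. The genome build and the counting settings are not given in the sources used here. Values per sample were not used here, so the depth of each library and the spread between replicates are unknown, and no standard deviation or interval could be given for any gene. The deposited fold changes were read as log2, because edgeR, named by the authors, reports log2 under this column name and because the smallest absolute value in the table is 1.00. The header does not say which group is the numerator. The sign was set from nac, amtB and glnK, genes that NtrC, the nitrogen starvation regulator, is known to switch on: all 3 have positive values, so a positive value is taken as higher in N_minus_5h. The direction of these 3 genes is therefore an assumption here and not a result. The direction of all other genes rests on it, and that of other genes under NtrC is not independent of it.

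The deposited table has 2237 rows, all coding sequences. Repeated rows of 4 locus tags, with equal values, were counted once, which leaves 2232 genes. No gene has an absolute log2 fold change under 1, whereas adjusted p-values above 0.05 are present, so the table was limited by fold change and not by p. A gene without a row changed by less than 2-fold, was not tested, or was left out for a reason not known here. For a given gene these cases cannot be separated. Because a Benjamini-Hochberg adjusted p is the p-value times the number of tests over its rank, the ratio of both columns gave the number of genes the authors adjusted over, 4247. At this number 68.0% of the genes had a whole rank within a tolerance of 1e-05, against 2.06% at the next best number. Of the 4247 genes 2015 have no row, so many genes without a row had been tested. Which ones is not known. All 2232 locus tags were found in the RefSeq gene table of assembly ASM584v2, which was used only for names and for the order of neighbouring genes. For 9 genes the name in the authors' deposited table differs from the RefSeq symbol, and the former is printed.

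The count test planned for read counts was not used, because the table holds no counts; the authors' adjusted p at a threshold of 0.05 took its place, as laid down for this case before the data were examined. The 43 gene lists were also fixed before the data were examined. Each was compared with all other genes of the table by cameraPR of limma 3.58.1 in R 4.3.3, with a preset correlation between genes of 0.01. It tests whether the mean statistic of a list is higher or lower than that of other genes. Its input was the normal score of the authors' p with the sign of the fold change, and Benjamini-Hochberg adjustment ran over the 42 lists with at least 3 members in the table. As the table holds only genes with at least 2-fold changes, the test compares a list with other such genes and not with the whole genome. Members under older names of the same gene were counted once. For counts adjusted over the list alone, members without a row were given a p of 1. Genes are not independent of each other within operons, groups of neighbouring genes read as 1 transcript, and a preset correlation covers this only in part.

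The 43 lists were ammonium assimilation and its regulators; NtrC-regulated uptake and breakdown of alternative nitrogen sources; putrescine uptake and breakdown; purine and allantoin breakdown; dipeptide and oligopeptide uptake; ribosomal proteins; translation factors and aminoacyl-tRNA synthetases. Further lists covered ribosome hibernation and ribosome rescue, transcription machinery, the RpoS general stress response, acid resistance, heat shock and proteolysis, flagella and chemotaxis, 6 sets of amino acid synthesis, sulfate assimilation and cysteine synthesis, purine and pyrimidine nucleotide synthesis, ATP synthase, NADH dehydrogenase I and cytochrome oxidases, the TCA cycle and glyoxylate shunt, and glycolysis and gluconeogenesis. The rest covered alternative carbon sources, glycogen metabolism, anaerobic respiration and fermentation, oxidative stress, the SOS response, envelope stress, toxin-antitoxin systems, and curli and biofilm matrix. They also covered type 1 fimbriae, cell division and DNA replication, phosphate starvation, ppGpp synthesis and stringent response factors, and cold shock proteins. The last were outer membrane proteins and porins, nucleoid-associated proteins, and iron uptake with iron-sulfur assembly under iron limitation, called the iron uptake list below.

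Genes were named by a rule fixed before the data were examined: the 12 with the largest positive and the 12 with the largest negative log2 fold change at an adjusted p below 0.05; per described list, the 2 members with the largest rise and the 2 with the largest fall at that threshold; and always glnA, glnK, amtB, nac, gdhA, gltB, rpoS, relA, rmf and fis. The parts of the rule on expression level and on agreement between replicates could not be applied without values per sample. The steps were tested on a simulated comparison of 4247 genes, of which only those changed at least 2-fold were kept. The number of tested genes was recovered as 4247, all 22 lists shifted by 2 on the log2 scale were called in the right direction, and 0 of 21 unshifted lists were called. The simulated genes were drawn independently of each other, so this does not measure false calls where genes of an operon move together. Alternatives were a stricter and an unadjusted threshold, a 4-fold threshold, a background without ribosomal protein and flagella genes, and 1 value per name stem. Added after seeing the data were higher preset correlations of 0.05 and 0.1, the log2 fold change as the statistic, Fisher's exact tests, counting every row, and counting all genes adjusted over. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots drawn with matplotlib 3.10.9.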

Results

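The transcriptome of Escherichia coli MG1655 growing on 9.35 mM NH4Cl was compared with that of cells held for 5 h in 0.935 mM NH4Cl, with 2 libraries in each group. The comparison asks how transcript levels differ between nitrogen-rich growth and nitrogen starvation. The starved cells had also been centrifuged, washed and incubated for longer. The labels do not say whether the N_plus cells were spun down and washed too, so the comparison may cover these steps together with the nitrogen supply and the longer incubation. All values are those of the authors' deposited table, which lists genes changed at least 2-fold, as N_minus_5h over N_plus. Per-library depth is unknown and no replicate error can be shown beside a fold change; the authors' adjusted p carries it.

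Under starvation, genes for scavenging nitrogen from pyrimidines and arginine, and genes of the general stress response and acid resistance, were higher. Genes for flagella, ribosomal proteins, ATP synthase and the synthesis of arginine and nucleotides were lower. At an adjusted p below 0.05, 1115 genes were higher and 974 were lower under starvation, 2089 of the 2232 genes in the authors' deposited table. The other 143 genes, 84 with positive and 59 with negative fold changes, did not pass. The median log2 fold change was 2.00 among the genes that rose and -1.86 among those that fell. A log2 fold change of at least 5 was reached by 53 genes, and 52 had one of -5 or less. Because the table starts at 2-fold, the count of changed genes and the count of genes changed at least 2-fold are the same. With a 4-fold threshold, 560 genes were higher and 446 lower.

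**Figure D1:**
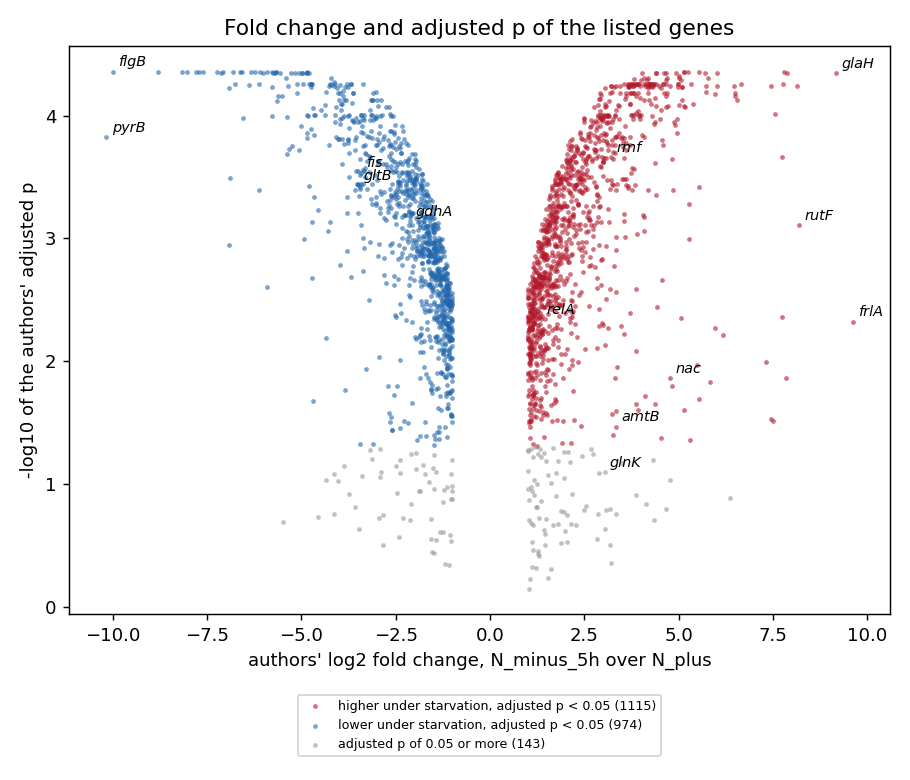
The authors' log2 fold change of N_minus_5h over N_plus on the horizontal axis is plotted against -log10 of the authors' adjusted p for the 2232 genes, 1 point per gene. Of these, 1115 are higher, 974 are lower and 143 do not pass an adjusted p of 0.05, and the gap in the middle is the 2-fold limit of the table.

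The largest rise in the authors' deposited table was that of frlA, for a fructoselysine transporter, with a log2 fold change of 9.61 (adjusted p = 0.00476), while the next gene of its operon, frlB, named after its value was seen, had 1.07. Also among the 12 largest rises were glaH and lhgD, for enzymes that break down glutarate, at 9.17 and 8.15 in the authors' deposited table. Their neighbours gabD and gabP, for the use of 4-aminobutyrate, had values of 7.55 and 7.78 there. Of the rut operon, for the breakdown of uracil, the authors' deposited table gave log2 fold changes of 8.18 for rutF, 7.87 for rutG, 7.84 for rutB, 7.74 for rutE and 7.51 for rutA. The other 2 of the 12 largest rises in the authors' deposited table were astE, of arginine breakdown, at 7.81 and yfjY, of a prophage region, at 7.73. The adjusted p of these 12 genes lay between 4.38e-05 and 0.0309 in the authors' deposited table.

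The largest fall in the authors' deposited table was that of pyrB, for the catalytic subunit of aspartate carbamoyltransferase in pyrimidine synthesis, with a log2 fold change of -10.17 (adjusted p = 0.000149). Its partner pyrI, for the regulatory subunit, stood at -7.62 in the authors' deposited table. The other 10 of the 12 largest falls were flagellar genes, for which the authors' deposited table gave -10.01 for flgB, -8.80 for flgC, -8.17 for flgD, -8.04 for flgE and -7.72 for flgF. In the authors' deposited table fliF stood at -7.79, fliI at -7.23, flgG at -7.12, fliL at -7.08 and fliO at -6.92.

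Genes of ammonium assimilation moved both ways. Of 12 members, 9 had a row, 4 rose, 4 fell and 1 did not pass. In the authors' deposited table nac, for a transcription regulator under NtrC, had a log2 fold change of 4.77 (adjusted p = 0.0137) and amtB, for the ammonium transporter, 3.33 (adjusted p = 0.0342). The signs of nac, amtB and glnK were used to set the direction of the table and are not independent evidence of it. The value of glnK, for the PII-like protein encoded beside amtB, was 3.04 in the authors' deposited table and did not pass (adjusted p = 0.0801). Genes for the glutamate synthase subunits fell, with -3.49 for gltB and -3.31 for gltD, as did gdhA, for glutamate dehydrogenase, with -2.12 in the authors' deposited table. No row is present for glnA, for glutamine synthetase. The mean statistic of the list was not found to differ from that of other genes (cameraPR adjusted p = 0.671). A test of the mean cannot show changes in opposite directions within a list. The list's median of 1.24 and mean of 0.42 are positive while the test's direction is down. The test compares signed normal scores of p and not fold changes.

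Among genes for alternative nitrogen sources under NtrC, 29 of 31 members with a row rose and 2 did not pass, with a median log2 fold change of 4.77 (cameraPR adjusted p = 0.000151). The direction of this list is not independent of the sign chosen for the table, which was set from other genes under NtrC. Adjusted over the list alone, 30 rose. The largest were rutF and rutG. In the authors' deposited table rutG had an adjusted p of 4.49e-05 and rutF one of 0.00078. Over the list as a whole, p-values were weak for the size of the fold changes. Among the 100 genes nearest in fold change, the median percentile of p was 82 for this list. It was 94 for the sulfate, 98 for the oxidative stress and 82 for the iron uptake list. Gene by gene these 4 lists passed an adjusted p of 0.05 for weak p and the cold shock list, at 83, did not; with 1 median per name stem only the oxidative stress list did, and the sulfate list could not be tested. Of the putrescine genes, 10 rose, 3 fell and 1 did not pass (cameraPR adjusted p = 0.0496). In the authors' deposited table gabP and gabD led, while puuB and puuC, of the glutamylated putrescine pathway, had log2 fold changes of -2.39 and -2.08. The call for this list was lost in 5 of 6 alternative settings, with an adjusted p of 0.345 at most. Of 16 purine and allantoin breakdown genes with a row, 15 rose and 1 did not pass, with a median of 3.10 (cameraPR adjusted p = 0.00104). The authors' deposited table gave 5.31 for guaD, for guanine deaminase, and 4.66 for hyi, for hydroxypyruvate isomerase. Of the peptide uptake genes 8 fell and 1, dtpB, rose (cameraPR adjusted p = 0.0411, lost in 3 of 6 settings). The authors' deposited table gave -3.74 for dppC, -3.44 for dppD and 2.56 for dtpB.

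The genes for translation fell together. All 54 ribosomal protein genes had a row; 53 fell and 1 did not pass, with a median log2 fold change of -2.86 (cameraPR adjusted p = 4.44e-11). With 1 value per name stem, which leaves 3 values, this list's adjusted p was 0.0753. The authors' deposited table gave -4.84 for rplM and -4.69 for rpsI. All 10 translation factors with a row fell (cameraPR adjusted p = 0.00389), with -3.18 for tufB and -2.32 for infA in the authors' deposited table. All 9 aminoacyl-tRNA synthetase genes with a row fell, of 23 members (cameraPR adjusted p = 0.00914, lost in 2 of 6 settings). The values of pheS and metG were -2.26 and -2.16 in the authors' deposited table. Of the transcription machinery 4 members fell and 1, rpoD, rose (cameraPR adjusted p = 0.145). The authors' deposited table gave -2.92 for rpoA, -1.98 for nusB and 2.18 for rpoD, the gene of the main sigma factor. Ribosome hibernation genes included 5 that rose, 1 that fell and 3 that did not pass (cameraPR adjusted p = 0.173). In the authors' deposited table ygaM stood at 4.30, elaB at 3.58 and rmf, for the ribosome modulation factor, at 3.20, and rsfS fell with -2.14. Of the ppGpp list only relA, for the main ppGpp synthetase, had a row, with 1.35 (adjusted p = 0.00453) in the authors' deposited table, so no test was made.

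Genes of several stress responses rose. Of 32 RpoS general stress genes with a row, 29 rose, 1 fell and 2 did not pass, with a median of 3.57 (cameraPR adjusted p = 5.82e-06). The authors' deposited table gave 6.01 for yciG, 5.06 for uspB and -2.17 for ldtC. No row is present for rpoS itself, the gene of the stress sigma factor. All 17 acid resistance genes with a row rose (cameraPR adjusted p = 0.00014), with 5.14 for yhiD and 4.10 for gadA in the authors' deposited table. Of 20 heat shock and proteolysis genes, 8 had no row, rpoH and lon among them. All 12 with a row rose (cameraPR adjusted p = 0.00683, lost in 1 of 6 settings), led in the authors' deposited table by hspQ at 3.62 and clpB at 3.20. Of 25 toxin-antitoxin genes with a row, 24 rose and 1 did not pass, with a median of 1.81 (cameraPR adjusted p = 0.000198). The authors' deposited table gave 4.69 for fic and 4.68 for relE.

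**Figure D2:**
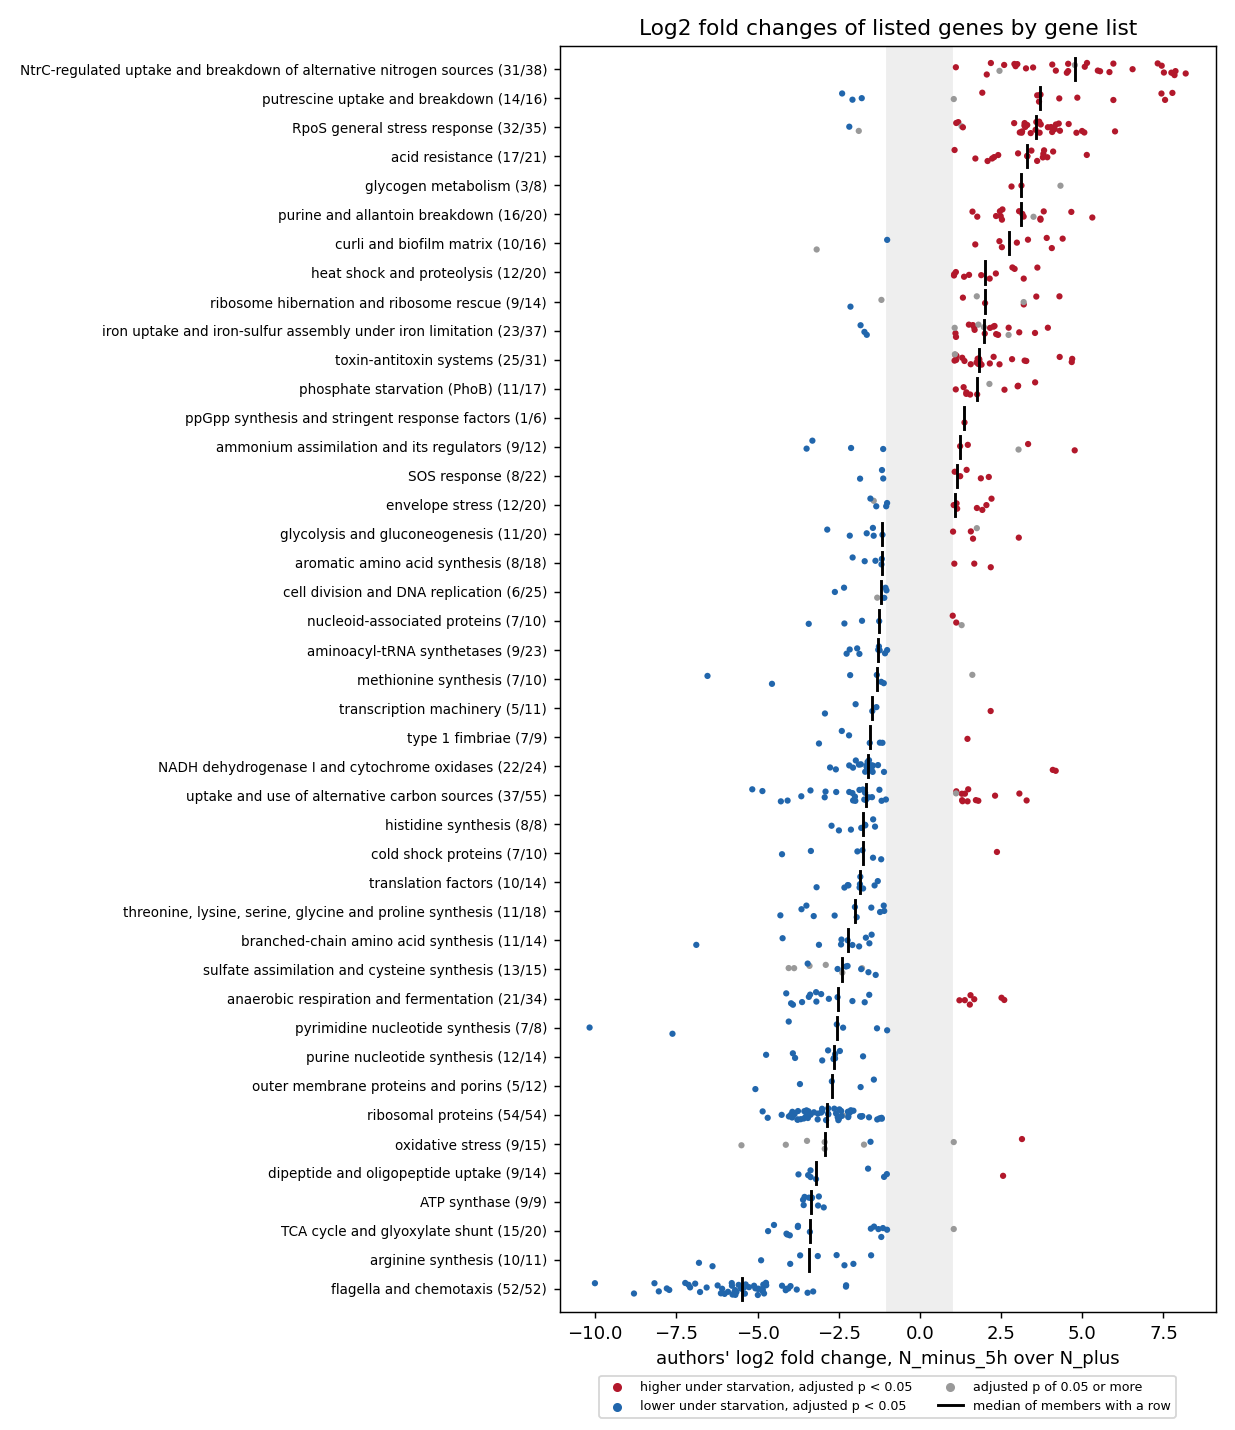
Each row is a gene list, with the members in the table over all members in brackets, and each point is the authors' log2 fold change of 1 gene, N_minus_5h over N_plus; bars mark medians and the grey band the range without rows. Medians ran from -5.46 for flagella and chemotaxis to 4.77 for genes of alternative nitrogen sources.

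Flagellar genes showed the lowest median of any list. All 52 members had a row and fell, with a median of -5.46 (cameraPR adjusted p = 1.58e-15), led by flgB and flgC. Type 1 fimbriae genes included 6 that fell and 1 that rose (cameraPR adjusted p = 0.0471, lost in 4 of 5 settings). The authors' deposited table gave -3.11 for fimB, -2.40 for fimA and 1.46 for fimE. Curli and biofilm genes included 8 that rose, 1 that fell and 1 that did not pass (cameraPR adjusted p = 0.0579), with 4.40 for csgE, 4.06 for csgF and -1.01 for csgC in the authors' deposited table. Of 12 outer membrane protein genes, 7 had no row, among them ompA, ompC and lpp. All 5 with a row fell (cameraPR adjusted p = 0.0198, lost in 2 of 6 settings). In the authors' deposited table these were led by ompF, for a porin, at -5.07 and nmpC, a pseudogene in RefSeq, at -3.69.

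Most listed genes for the synthesis of amino acids and nucleotides fell. All 10 arginine synthesis genes with a row fell, with a median of -3.42 (cameraPR adjusted p = 0.000332). The authors' deposited table gave -6.80 for carA and -6.39 for carB. All 11 branched-chain genes with a row fell (cameraPR adjusted p = 0.00114), with -6.89 for ilvM and -4.23 for ilvC in the authors' deposited table. All 8 histidine genes fell (cameraPR adjusted p = 0.0171, lost in 1 of 5 settings), with -2.72 for hisG and -2.49 for hisD in the authors' deposited table. Of the methionine genes 6 fell and 1 did not pass (cameraPR adjusted p = 0.0404, lost in 3 of 5 settings), and the authors' deposited table gave -6.54 for metE and -4.56 for metF. All 11 threonine, lysine, serine, glycine and proline genes with a row fell, of 18 members (cameraPR adjusted p = 0.00169). The authors' deposited table gave -4.30 for lysA and -3.65 for glyA. Aromatic amino acid genes split, with 5 lower and 3 higher (cameraPR adjusted p = 0.372). The authors' deposited table gave -2.07 for aroF, -1.70 for tyrA, 2.18 for trpD and 1.67 for trpC.

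Of 13 sulfate and cysteine genes with a row, 7 fell and 6 did not pass (cameraPR adjusted p = 0.0238, lost in 2 of 5 settings). Adjusted over the list alone, 4 fell. The authors' deposited table gave -3.46 for cysJ and -2.53 for cysI, of sulfite reductase. All 12 purine synthesis genes with a row fell, with a median of -2.65 (cameraPR adjusted p = 0.000279), with -4.74 for purT and -3.91 for purM in the authors' deposited table. All 7 pyrimidine synthesis genes with a row fell (cameraPR adjusted p = 0.00639), led by pyrB and pyrI.

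Genes of energy metabolism were mostly lower. All 9 ATP synthase genes fell, with a median of -3.34 (cameraPR adjusted p = 0.00114) and with -3.60 for atpF and -3.58 for atpH in the authors' deposited table. Among NADH dehydrogenase I and cytochrome oxidase genes 20 fell and 2 rose (cameraPR adjusted p = 0.00171, lost in 2 of 6 settings). The authors' deposited table gave -2.77 for cyoB and -2.59 for cyoA, of the oxidase used with ample oxygen, and 4.18 for appC and 4.09 for appB, of another oxidase. Of the TCA cycle genes 14 fell and 1 did not pass (cameraPR adjusted p = 0.000891), with -4.68 for sdhB and -4.49 for sucD in the authors' deposited table. Glycolysis and gluconeogenesis genes went both ways, with 6 lower, 4 higher and 1 not passing (cameraPR adjusted p = 0.562). The authors' deposited table gave -2.85 for pck, -2.16 for ptsG, 3.05 for fbaB and 1.64 for gpmA. Alternative carbon source genes included 24 that fell, 12 that rose and 1 that did not pass (cameraPR adjusted p = 0.0324, lost in 3 of 6 settings). Maltose genes led the falls in the authors' deposited table, with -5.16 for malK and -4.85 for malE, and xylose genes the rises, with 3.29 for xylA and 3.06 for xylB. Of the glycogen genes 2 rose and 1 did not pass (cameraPR adjusted p = 0.164), with 3.13 for glgP and 2.82 for glgA in the authors' deposited table. Anaerobic respiration and fermentation genes included 14 that fell and 7 that rose (cameraPR adjusted p = 0.0411, lost in 4 of 6 settings). The authors' deposited table gave -4.12 for dmsA, -3.97 for hybA, 2.60 for nrdG and 2.51 for nrdD.

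The remaining lists, apart from phosphate starvation, were mixed or short. Of the iron uptake list, which includes 6 suf genes of iron-sulfur assembly, 23 of 37 members had a row. The 14 without a row include entA, entB, entC and fepA. Of the 23, 16 rose, 3 fell and 4 did not pass (cameraPR adjusted p = 0.0377, lost in 4 of 6 settings). Adjusted over the list alone 15 rose. The authors' deposited table gave 3.94 for fhuF, 3.54 for fecI, -1.83 for fepG and -1.71 for fiu. Of 9 oxidative stress genes with a row, 7 did not pass, soxR rose and oxyR fell, with 3.14 and -1.52 in the authors' deposited table (cameraPR adjusted p = 0.449). Those that did not pass, named outside the rule, were grxA at -5.49, katG at -4.13, trxC at -3.48 and ahpF at -2.93 there. The others were ahpC at -2.93, gor at -1.72 and acnA at 1.04, and the median of the list was -2.93. SOS genes included 5 that rose and 3 that fell (cameraPR adjusted p = 0.601), with 2.12 for umuC, 1.88 for umuD, -1.84 for dinD and -1.17 for dinI in the authors' deposited table. Envelope stress genes included 7 that rose, 4 that fell and 1 that did not pass (cameraPR adjusted p = 0.592), with 2.20 for spy, 2.05 for pspG, -1.52 for yccA and -1.34 for fkpA in the authors' deposited table. Of 17 phosphate starvation genes, 6 had no row, among them phoA and pstS. Of the others 10 rose and 1 did not pass, led in the authors' deposited table by phoH at 3.55 and ugpA at 3.02. This call (cameraPR adjusted p = 0.00914) was lost in 2 of 6 settings, 1 value per name stem among them. Cell division and replication genes included 5 that fell and 1 that did not pass, of 25 members (cameraPR adjusted p = 0.0471, lost in 4 of 6 settings), with -2.62 for dnaB and -2.34 for gyrA in the authors' deposited table. Of the cold shock genes 6 fell and 1, cspD, rose (cameraPR adjusted p = 0.108), with -4.25 for cspF, -3.36 for cspG and 2.37 for cspD in the authors' deposited table. Nucleoid protein genes included 4 that fell, 2 that rose and 1 that did not pass (cameraPR adjusted p = 0.371). The authors' deposited table gave -3.42 for fis, -2.32 for hupB, 1.12 for cbpA and 1.01 for ihfA.

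Altogether 30 of the 42 lists tested passed, 9 higher and 21 lower, and 14 of the 30 kept their call in every alternative test of direction that could be run for them. For 40 of the 43 lists the counts adjusted over the list alone equalled those over all genes tested. No correlation between genes could be estimated without values per sample.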

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

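The higher preset correlations, the fold change as the statistic, the Fisher's exact tests, counting every row and counting all genes adjusted over were chosen after seeing the data. The number of changed genes was 1898 at an adjusted p below 0.01, 2120 at an unadjusted p below 0.05, 2094 with every row counted and at least 2703 over all genes adjusted over, of which at least 614 have no row. With a 4-fold threshold 1006 genes remained, 560 higher and 446 lower, because a stricter threshold removes genes. Of the 30 lists called, 11 were called with 1 value per name stem, where 21 of them could be tested, 15 with a preset correlation of 0.1, and 15 by Fisher's exact test of having a row, which asks another question and calls 1 list for too few rows. Fewer values enter with 1 value per stem, and the cause of the other shifts was not tested. Within 1.5 times of 30 were 26 lists with the smaller background, 21 with a preset correlation of 0.05, 29 with the fold change as the statistic and 26 by Fisher's exact test of direction. No called list changed direction in these settings, whereas ammonium assimilation and envelope stress, not called, did. With the fold change as the statistic oxidative stress (adjusted p = 0.0358) and curli (adjusted p = 0.0457) were called too. Of 132 genes named by the rule that passed, 10 lost their call at an adjusted p below 0.01. No paired analysis was possible because the table holds 1 comparison and no values per sample. For the same reason other normalizations, tools, low-count filters, pseudocounts, leaving out each replicate, rRNA removal, a test against a fold threshold, an estimated correlation and a self-contained list test were not run. Depth is unknown, so it cannot be said which genes it limits.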

Other observations

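Several groups of neighbouring genes outside the fixed lists also changed together; they were chosen after their values were seen. In RefSeq order, 28 runs of at least 7 neighbouring coding genes changed in 1 direction with an adjusted p below 0.05, 14 higher and 14 lower. In 1000 shuffles of the gene order there were at most 3 such runs. The shuffles moved genes singly and split operons, so more runs and more like pairs than in a shuffle would arise from operons alone. Of the 28, 6 held no gene of the fixed lists. The run from yahN to prpE, which includes the propionate breakdown genes, rose with a median log2 fold change of 4.10, and prpB reached 5.53 in the authors' deposited table. Runs of type II secretion genes from gspA to gspH, with a median of 2.53, of hydrogenase 4 genes from hyfA to hyfG, with 2.19, of colanic acid capsule genes from cpsB to wcaD, with 2.09, and of CRISPR-associated genes from cas1 to cas3, with 1.24, rose as well. The run from ccmG to napA, for cytochrome c maturation and periplasmic nitrate reductase, fell with a median of -1.81, and napA reached -3.64 in the authors' deposited table. Across the genome 1063 of 1280 neighbouring pairs that both passed changed in the same direction, 83.0%, against at most 54.6% in a shuffle.

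The largest rise had no counterpart of its size next to it. In the authors' deposited table frlA stood at 9.61, while frlB, the next gene of its operon, stood at 1.07 and frlC has no row. Of the genes on either side of yfjY, which stood at 7.73, yfjX had -1.82 and ypjJ 3.35, which did not pass (adjusted p = 0.176), in the authors' deposited table. By contrast glaH, lhgD and gabD, which are neighbours, lay between 7.55 and 9.17 in the authors' deposited table.

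All tests of the next 2 patterns were chosen after the result was seen; the test of the last pattern was written before its summary was computed, though borD and some other values had been seen. Genes of the NtrC, sulfate, oxidative stress and iron uptake lists had weak p-values for their fold changes; these are all the lists above the middle that passed an adjusted p of 0.05 in this test, gene by gene, while the flagella and arginine synthesis lists passed below it. Each gene's p was ranked among the 100 genes nearest in fold change with the same sign, other members of its list included. Only 53 genes that passed had a log2 fold change of at least 5, so the match may be loose for the largest rises, such as the rut genes. The median percentile over the 76 members was 86, where 50 would be the middle, and 19 of the 76 did not pass an adjusted p of 0.05. Libraries of 1 group that differ alike in all genes would weaken the p of genes of like fold as well and leave the lists near 50. With 1 median per name stem, the oxidative stress list had a median percentile of 97, with an adjusted p of 0.0062 in this test. This does not exclude such a difference between libraries or a chance draw, because the test was chosen after the pattern was seen. The 9 genes of this list also gave 8 stems, so members that move together would still count as separate draws. Both explanations stay open for the other 3 lists too. With 1 median per name stem the NtrC list gave 0.0651 at a percentile of 82.5 and the iron list 0.0744 at 82. Gene by gene they gave 0.0021 and 0.00504, and the sulfate list has too few stems. Few reads behind these genes, or cultures of 1 group at different stages of these responses, may each account for the weak p-values as well. They cannot be told apart without values per sample.

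Within the nitrogen and sulfate operons the p-values tended to fall from the first gene to the last. In the rut operon the authors' deposited table gave a p of 0.0184 for rutA and 4.12e-07 for rutG. Over the 8 operons of these lists with at least 3 rows, all 8 had a negative rank correlation between position and p, with a mean of -0.93. The pattern was found in these operons, so a permutation of their order (p = 1e-05) does not exclude chance. The glt operon, with 2 rows, was left out and went the other way. Its p in the authors' deposited table was 0.000157 for gltI and 0.00408 for gltJ, the next gene. A fall of p along operons in general is argued against by other known operons, chosen by hand and split by direction. The gap between them and the 8 does not show a trait of the 8, which were those the pattern was found in. The 5 nitrogen operons, which rose, had a mean of -0.93 against 0.03 in 24 other operons that rose (bootstrap 95% interval -0.22 to 0.29), and the 3 sulfate operons, which fell, one of -0.93 against 0.34 in 24 others that fell (bootstrap 95% interval 0.15 to 0.52). Still, 11 of the other rising and 4 of the other falling operons had negative values too. Among them were suf, whose genes belong to the iron uptake list, hde-yhiD and lsr, and dpp and nuo. Of the other rising operons 3 lay at or below the mean of the nitrogen operons, against 0 of the falling ones for the sulfate operons. The 4 operons of the putrescine and purine lists, not in this comparison, went both ways. A candidate explanation that stays open beside chance is that replicates differed in how far these responses had run, which values per sample would be needed to test.

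Of all genes with a row, 1199 of 2232 had positive values. Among words in the descriptions, looked at after values were seen and without a test, these were 27 of 29 genes with toxin, antitoxins included, 44 of 56 with uncharacterized, 93 of 128 with DUF, a domain of unknown function, 22 of 31 with fimbria and 5 of 8 with transposase, against 0 of 35 with flagell and 1 of 60 with ribosomal. A common relative lift of scarce transcripts, or reads from carried-over DNA, may give such shares and predicts alike values for prophage genes. Of 12 genes with a row and the word prophage in their description, 8 were higher and 4 lower. They ran from -6.62 for borD to 2.58 for rzoR in the authors' deposited table, with an interquartile range of 3.02. Genes of prophage regions described without that word, such as yfjY at 7.73 in the authors' deposited table, were not counted. The share lower and the range both lie on the side that argues against such a lift or carry-over. That side was at least 25% lower, or a range above 2, as set before the result was seen. With no absolute value under 1 in the table, quartiles of opposite sign lie at least 2 apart, so these are not separate evidence. Neither lies there by more than its spread. The bootstrap 95% interval of the range ran from 0.23 to 4.71. The exact 95% interval of the share lower ran from 9.9% to 65.1%. This leaves the lift or carry-over open, and the 2-fold limit of the table hides prophage genes that moved less. No biological explanation was tested for this pattern.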
